A study of Homo sapiens with 9 samples.

How the data were processed

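Messenger RNA was measured in 9 libraries of BJAB, an established human B-cell lymphoma line, in 3 groups of 3: untreated cells, cells given BAFF, and cells given BAFF together with the compound RS47. Per the labels, total RNA was isolated with a mirVana kit, its integrity was checked on a Bioanalyzer, and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps the strand. The genome build was GRCh38, per the submitters' processing notes. The aligner, the counting program, the annotation release and the use of strand in counting are not given in the sources used here. Doses and treatment times are likewise not given in the sources used here.

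The deposited count table holds whole-number read counts per gene for 20030 genes, and these counts were the basis of every test reported. Totals ran from 17119460 to 20211171 counts per library, so that 1 count corresponded to 0.0492 to 0.0582 CPM, the unit of counts scaled to one common library size, and 3161 genes had no count in any library. The deposited FPKM table holds the authors' values scaled for transcript length and library depth, which served only as an alternative input. The authors' deposited comparison tables list mean scaled expression signal per group, a fold change (ratio of group means), its log2 value, and p-values with adjusted p-values, per the file headers. The test behind these tables and its adjustment are not given in the sources used here. The authors' Up and Down calls, stored as text in a deposited summary table, coincided with a raw p-value under 0.05 and a 2-fold change. Gene symbols and NCBI gene identifiers were taken from the deposited tables, and positions of 19741 genes from the RefSeq annotation of GRCh38, matched on the identifier.

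Groups were taken from the labels. Counts were filtered with filterByExpr, which left 11871 genes, scaled with TMM factors and fitted over all 9 libraries with a quasi-likelihood model in edgeR 4.0.16 (limma 3.58.1, R 4.3.3). The 3 pairwise contrasts were tested with glmQLFTest, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2 scale with their standard errors (SE), and expression levels are TMM-scaled CPM given as mean ± SD of 3 libraries. The common biological coefficient of variation was 2.31%. Replicate libraries differed by more than sampling noise, with a chi-square per gene between 1.69 and 2.48 in the 9 pairs, so each was counted as its own sample. The labels do not say whether the 3 libraries of a group came from separate cultures. All p-values therefore measure only the spread between these libraries, which may be technical.

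A total of 34 gene lists were written before the data were examined, and 32 of them had at least 5 members past the filter. These were tested with camera, two-sided, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The mitochondrially encoded genes had no rows in the count table, and 4 of 12 epithelial markers passed the filter, so these lists were not tested. Members of lists were also counted by the test per gene, adjusted over all genes and adjusted over the list alone. Median changes with RS47 were taken over the genes raised or lowered by BAFF, beside simulated libraries without an effect and with each BAFF library held out in turn, since both comparisons share the BAFF libraries. Fold thresholds of 2 were applied to the fitted fold change after the test.

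Genes were named by a rule written before the data were examined. For each comparison it took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean logCPM of at least 1 and no overlap between the groups. It added 11 fixed genes of the BAFF and NF-kB pathways, whatever their values: RELB, NFKB2, NFKB1, RELA, REL, TNFRSF13C, TNFSF13B, MAP3K14, TRAF3, BIRC3 and ICAM1. It also added up to 4 members with the smallest p of each list described. Of genes raised by BAFF and lowered with RS47, and of those with the opposite course, it added the 10 with the largest change with BAFF. Genes without a symbol, or named only by clone or locus, were passed over. Some genes that the rule selected are not reported here by name; they stayed in the tests and in the counts of list members.

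The edgeR step was tested on simulated counts of 11718 genes in which 65 or 66 genes at each of 3 sizes were changed. For BAFF against untreated it recovered 75.4% of genes changed by 0.5 on the log2 scale, 87.9% of those changed by 1 and 98.5% of those changed by 2. In the same simulation 17 unchanged genes were called, 8.99% of the calls. Camera called the planted list and none of 30 unchanged lists. Genes were simulated independently of each other, so this could not show false calls that arise from correlation between genes.

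Alternatives were DESeq2 size factors, no scaling beyond library size, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter of 1 CPM in 3 libraries, a replicate block, and fits on the 6 libraries of a comparison alone. Others were limma on log2 of FPKM with a pseudocount of 1 or 0.1, for genes with an FPKM of at least 1 in 3 libraries. A threshold of 0.01, a 2-fold threshold and leaving out each library in turn were also applied. Leaving out both libraries that stood apart, and restricting 2-fold changes to genes with a mean logCPM of at least 3 or 5, were chosen after the data had been seen, as was repeating the alternatives for the 2-fold results. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.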

Results

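Gene expression was profiled by RNA sequencing in BJAB cells, a human B-cell lymphoma line, left untreated, given BAFF, or given BAFF with RS47, a small molecule directed at RelB. BAFF is a TNF family cytokine that activates the non-canonical NF-kB pathway in B cells, in which RelB pairs with the p52 product of NFKB2. Each group held 3 libraries. Totals ran from 17411309 to 19210419 counts in untreated libraries, 17119460 to 20211171 with BAFF and 18606465 to 19048824 with BAFF and RS47. Principal component 1 held 60.2% of the variance and component 2 held 22.8%. Component 3, with 7.89%, set untreated replicate 3 and BAFF with RS47 replicate 2 apart from the other libraries. These libraries also listed fewer genes with a count, 13473 and 13689. The other untreated libraries listed 14314 and 14342, and the other RS47 libraries 14316 and 14479. Each BAFF library listed more than any library of the other groups, 14670 to 14948.

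The first comparison asked which genes responded to BAFF. NFKB2 (NCBI gene 4791; GRCh38 chromosome 10, 102394110 to 102402529) rose from 136 ± 5.32 to 260 ± 7.58 CPM (SD, n = 3). RELB (NCBI gene 5971; chromosome 19, 45001464 to 45038192) rose from 182 ± 8.56 to 282 ± 4.12 CPM. Of 34 NF-kB feedback and target genes, 29 rose, 1 fell and 4 did not pass, with 13 rises of 2-fold or more.

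Among these target genes, EBI3, a cytokine subunit, rose from 74.9 ± 1.47 to 241 ± 6.25 CPM. TNFAIP3, which encodes a deubiquitinase that restrains NF-kB, rose from 133 ± 4.43 to 304 ± 3.29 CPM, and NFKBIA, the inhibitor IkBα, from 143 ± 2.12 to 297 ± 5.85 CPM. ICAM1, an adhesion molecule, rose by 1.16 on the log2 scale (SE 0.03, edgeR adjusted p = 9.38e-24). In the list of pathway components 16 of 25 genes rose and 5 fell. NFKB1 rose by 0.67 and REL by 0.46. RELA changed by 0.09 (edgeR adjusted p = 0.0436) and TRAF3, an inhibitory adaptor, by 0.07 (edgeR adjusted p = 0.028), calls lost under 10 and 8 of 19 alternatives, 7 and 4 of them leaving out 1 library. MAP3K14, which encodes the kinase NIK, changed by -0.23 and BIRC3, a ubiquitin ligase gene of the pathway, by -0.35. TNFRSF13C, the BAFF receptor gene, stood at 19.7 ± 1.78 CPM without and 18.1 ± 1.10 CPM with BAFF (edgeR adjusted p = 0.218). TNFSF13B, which encodes BAFF, did not pass the filter, with 7 counts in the untreated, 22 in the BAFF and 24 in the BAFF and RS47 libraries together.

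The non-canonical NF-kB target list had 13 of 18 genes raised and 2 lowered. CCR7, a receptor that guides lymphocytes to lymph nodes, rose from 121 ± 1.29 to 449 ± 3.35 CPM, and BCL2L1, a survival gene, from 102 ± 2.59 to 256 ± 3.44 CPM. Of 32 chemokine, cytokine and receptor genes, 24 rose and 5 fell, with CCL5 rising from 4.38 ± 0.205 to 28.8 ± 1.75 CPM. Of 32 interferon response genes 29 rose and 1 fell. IFI44L, one of them, rose from 42.1 ± 1.43 to 189 ± 4.41 CPM. Antigen presentation genes rose in 25 of 27 cases, among them CD40, from 190 ± 0.752 to 321 ± 2.48 CPM. HLA-DRA, HLA-DQA1 and HLA-E also rose, although HLA genes can share reads with near-identical copies, which leaves their values uncertain. The adhesion list held 11 rises and 5 falls, with ITGB2, an integrin subunit, rising by 2.44 (SE 0.08).

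Genes of the germinal centre B cell fell in 12 of 16 cases and rose in 2. MME, which encodes the surface marker CD10, fell from 218 ± 2.76 to 107 ± 1.27 CPM. MYC fell from 346 ± 7.14 to 152 ± 2.99 CPM, and is among the 23 of 28 genes of the MYC and ribosome biogenesis list that fell (median -0.225). B cell identity genes fell in 14 of 22 cases (median -0.23), including the coactivator POU2AF1, by 0.73 on the log2 scale. JCHAIN, which joins polymeric antibodies, fell from 629 ± 8.24 to 203 ± 6.45 CPM. Falls also covered 29 of 35 nuclear oxidative phosphorylation genes (median -0.19), 26 of 35 G2/M genes (-0.20), 18 of 23 cholesterol biosynthesis genes (-0.32) and 8 of 11 fatty acid synthesis genes (-0.24).

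Rises were also found for 17 of 22 genes of the unfolded protein response (median 0.28), 23 of 31 of the ATF4 stress response (0.25) and 8 of 13 anti-apoptotic genes (0.17). YAP1 (NCBI gene 10413; chromosome 11, 102110447 to 102233424), a transcriptional coactivator, rose from 1.36 ± 0.354 to 26.0 ± 1.69 CPM. GDF15, a stress-induced cytokine, had 12 counts in the untreated and 260 in the BAFF libraries together, a ratio of 21.5 with a 95% counting interval of 12.1 to 42.1. CD200, an immune checkpoint ligand, rose 12.3-fold by counts (95% counting interval 8.24 to 19.1). P2RX7, an ATP-gated channel, rose from 1.51 ± 0.0999 to 18.6 ± 0.490 CPM. The largest falls by the naming rule included NCKAP1, an actin regulator, with a change of -2.13 (SE 0.05), RASSF6 with -1.76 (SE 0.03) and TNFRSF13B, a further BAFF receptor gene, with -1.82 (SE 0.09).

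Markers of other cell types moved with BAFF as well. Of the T and NK cell markers 5 of 6 tested rose, with CD3E at 1.63 ± 0.414 and 6.19 ± 0.473 CPM, and 4 of 6 fibroblast and endothelial markers rose, with COL1A1 at 53.1 ± 2.04 and 173 ± 6.58 CPM. Of 6 myeloid markers 3 rose, and that list did not pass (camera adjusted p = 0.525). The epithelial list was not tested, and 3 of its 12 markers rose 2-fold or more.

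In all, 7035 of 11871 genes differed between BAFF and untreated cells by the edgeR quasi-likelihood test, 3434 higher and 3601 lower, a balance that turned to 3598 and 3409 when libraries were scaled by size alone. Most changes were small: 740 genes rose and 104 fell by 2-fold or more. Among genes with a mean logCPM of at least 3, a cut chosen after the data had been seen, 163 rose and 38 fell 2-fold. On the FPKM scale with a pseudocount of 1, 149 genes changed 2-fold. Without both libraries that stood apart, an alternative chosen after the data had been seen, 6751 genes were called. The authors' deposited table has 6162 genes with an adjusted p-value under 0.05, among 16495 genes with a p-value, a wider set than the 11871 tested here.

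Camera called 21 of 32 lists, 12 upward and 9 downward. These included NF-kB feedback and target genes (adjusted p = 3.96e-38), antigen presentation (9.32e-26), non-canonical targets (5.95e-18) and interferon response (2.15e-17). Among the lists called downward was the germinal centre B cell list (6.32e-11). Camera with an estimated correlation gave these lists adjusted p of 0.0011, 0.00492, 0.00357, 0.00403 and 0.00357, in this order. Some lists share members, so their calls are not independent of each other. EBI3 is in both NF-kB target lists, and CD40 is in the pathway component and antigen presentation lists. With an estimated correlation 15 lists passed and 6 did not. The estimated-correlation adjusted p was 0.0839 for oxidative phosphorylation, for glycolysis and hypoxia and for the fibroblast and endothelial markers, 0.0514 for adhesion, 0.0954 for T and NK cell markers and 0.173 for heat shock. The glycolysis and hypoxia list was called downward, with 13 of 29 genes lower and 9 higher, while its median of 0.04 and mean of 0.05 were positive. Of 17 heat shock genes 10 fell and 3 rose. The uncalled lists were immediate early genes (camera adjusted p = 0.0881), NRF2 (0.0587), plasma cell differentiation (0.161), p53 targets (0.817), pro-apoptotic genes (0.325), G1/S (0.393), cytosolic ribosomal proteins (0.267), AhR response (0.602), metallothioneins and zinc (0.267), histones (0.715) and the myeloid markers. For NRF2 and p53 targets the median was negative and the mean and test positive, and for plasma cell genes the median and mean were positive and the test negative. Adjusted over the list alone, 30 NF-kB feedback and target genes, 15 non-canonical targets, 31 interferon genes, 27 antigen presentation genes and 14 germinal centre genes passed, against 30, 15, 30, 27 and 14 adjusted over all genes.

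**Figure D1:**
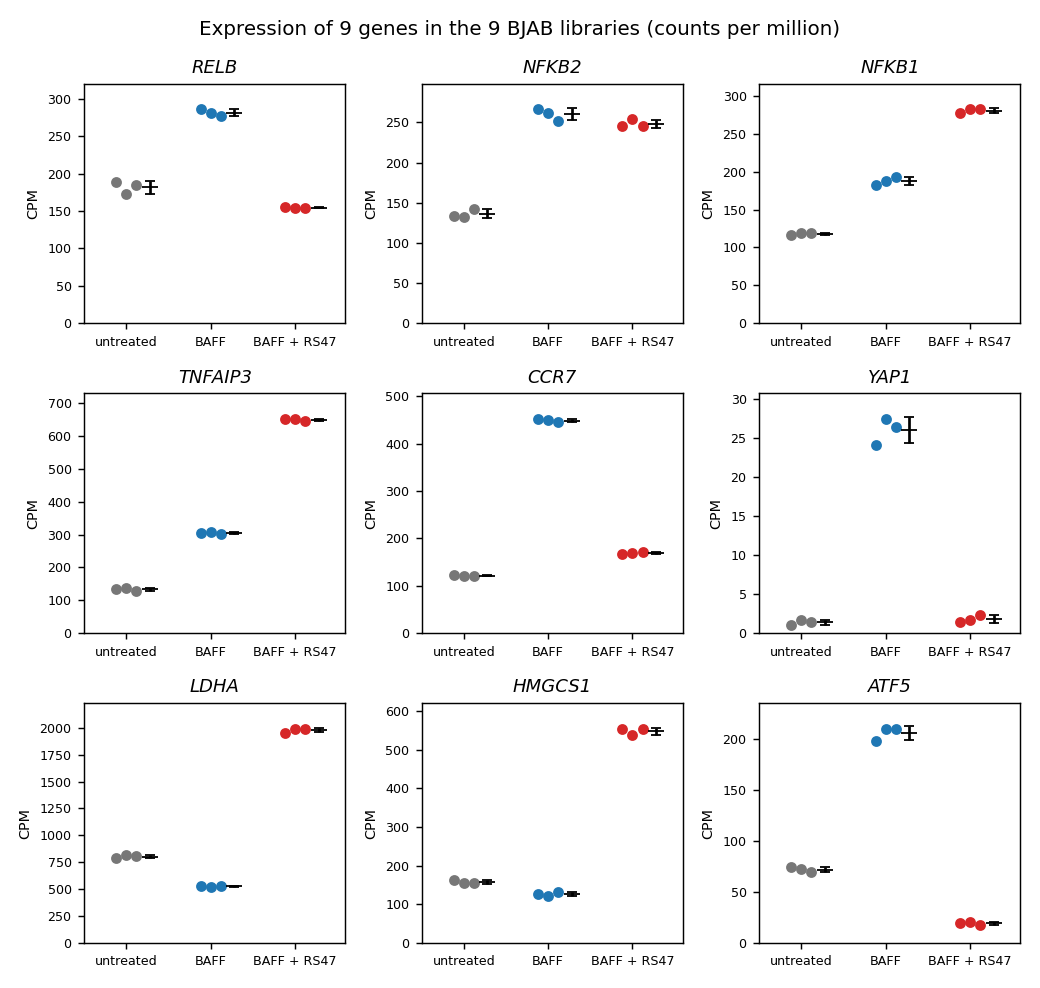
Expression of 9 genes in CPM (vertical axes, from 0) in untreated, BAFF, and BAFF with RS47 libraries; each point is a library and the black bar is the mean ± SD of 3. RELB and CCR7 were higher with BAFF and lower again with RS47, whereas NFKB1 and TNFAIP3 rose further, TNFAIP3 to 650 ± 2.85 CPM.

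The second comparison asked what RS47 changed in BAFF-treated cells. RELB fell from 282 ± 4.12 to 155 ± 0.481 CPM, below the untreated level of 182 ± 8.56 CPM. NFKB2 stayed high, at 249 ± 5.03 CPM, a change of -0.07 (SE 0.03, edgeR adjusted p = 0.0304) whose call was lost under 10 of 19 alternatives, 4 of them leaving out 1 library. NFKB1 rose from 188 ± 5.53 to 281 ± 3.06 CPM and RELA from 75.6 ± 0.999 to 116 ± 2.82 CPM. Of the 34 NF-kB feedback and target genes 20 rose, 12 fell and 2 did not pass, a list that camera did not call (median 0.24, adjusted p = 0.169).

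TNFAIP3 rose by a further 1.10 on the log2 scale (SE 0.02), TNIP1, another NF-kB restraint, by 0.89 and CD40 by 0.61, while NFKBIA changed by -0.77 and CFLAR, an inhibitor of death receptor signalling, by -1.36 (SE 0.03). ICAM1 was at 248 ± 5.43 CPM with RS47 and 244 ± 6.73 CPM without (edgeR adjusted p = 0.394). REL rose by 0.39 and TRAF3 by 0.20, and TNFRSF13C changed by -0.72 and BIRC3 by -0.22. MAP3K14 differed by 0.003 (SE 0.05, edgeR adjusted p = 0.954), and its sign turned to -0.005 when libraries were scaled by size alone and under 4 other alternatives, the lowest being -0.03 without BAFF with RS47 replicate 2. Of the pathway components 15 of 25 rose and 8 fell (camera adjusted p = 0.446). Non-canonical targets fell in 11 of 18 cases and rose in 5 (camera adjusted p = 0.345). CCR7 fell from 449 ± 3.35 to 169 ± 2.67 CPM, whereas CCL22, a chemokine for T cells, rose from 47.8 ± 2.06 to 294 ± 2.91 CPM. Chemokine and receptor genes split into 13 rises and 12 falls, and interferon genes into 16 rises and 12 falls, with CXCL10 falling by 1.30 and IFIH1 rising by 0.97.

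Genes of glycolysis and hypoxia rose in 27 of 29 cases, 19 of them by 2-fold or more. PFKFB4 (NCBI gene 5210; chromosome 3, 48517684 to 48563136), a regulator of glycolytic flux, rose from 5.17 ± 0.857 to 321 ± 7.55 CPM. LDHA, lactate dehydrogenase, rose from 524 ± 2.50 to 1978 ± 19.5 CPM, and KDM3A, a hypoxia-responsive demethylase, from 70.3 ± 1.69 to 353 ± 1.39 CPM. Cholesterol biosynthesis genes rose in 21 of 23 cases, with HMGCS1, an early enzyme of the pathway, going from 126 ± 5.77 to 548 ± 9.03 CPM, and fatty acid synthesis genes in 10 of 11, with SCD going from 497 ± 4.78 to 1863 ± 8.0 CPM. All 6 tested genes of the AhR response rose, among them TIPARP by 1.79 (SE 0.06). Immediate early genes rose in 18 of 21 cases, G1/S and DNA replication genes in 32 of 34, and heat shock genes in 10 of 17, with HSPA8 rising from 555 ± 7.44 to 1427 ± 42.2 CPM.

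Genes of the ATF4 stress response fell in 26 of 31 cases. WARS, a tRNA synthetase, fell from 1124 ± 9.23 to 262 ± 2.94 CPM, and ATF5, a transcription factor of this response, from 206 ± 6.65 to 19.4 ± 1.57 CPM. MYC and ribosome biogenesis genes fell in 27 of 28 cases, including POLR1B, an RNA polymerase I subunit, by 1.38 (SE 0.03). B cell identity genes fell in 16 of 22 cases, with PAX5, a lineage transcription factor, going from 336 ± 1.38 to 166 ± 4.49 CPM. Antigen presentation genes fell in 19 of 27 cases, with CD74 at 4408 ± 21.5 and 2700 ± 54.9 CPM, and plasma cell genes in 11 of 15, with MZB1 falling by 1.45 (SE 0.03). Ribosomal protein genes fell in 33 of 43 cases by small amounts (median -0.17).

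All 10 histone genes tested fell, HIST1H2BK from 40.4 ± 2.17 to 3.94 ± 0.491 CPM. Histone genes share reads with near-identical copies, and most of their transcripts carry no poly(A) tail and are lost in a poly(A)-selected library, so these values are uncertain. ALPK2, a kinase gene, fell from 182 ± 1.72 to 8.63 ± 0.199 CPM and YAP1 from 26.0 ± 1.69 to 1.81 ± 0.490 CPM. CD200 had 323 counts in the BAFF and 5 in the RS47 libraries together, a ratio of 66.3 with a 95% counting interval of 28.1 to 206. ITIH5, with 6 counts against 356, was 57.8-fold higher with RS47 (95% counting interval 26.3 to 159).

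RS47 changed 9416 of 11871 genes in BAFF-treated cells by the edgeR quasi-likelihood test, 4550 upward and 4866 downward, with 782 rises and 1346 falls of 2-fold or more. Among genes with a mean logCPM of at least 3, a cut chosen after the data had been seen, 465 rose and 520 fell 2-fold, and at 5 or more 271 rose and 229 fell. Without both libraries that stood apart 9344 were called. The authors' deposited table has 9052 genes with an adjusted p-value under 0.05, among 16598 genes with a p-value, again a wider set than the 11871. Camera called 14 of 32 lists, 7 in each direction, led by glycolysis and hypoxia (adjusted p = 1.00e-54), cholesterol biosynthesis (3.38e-35), G1/S (8.79e-19) and the ATF4 response (1.15e-17). With an estimated correlation 8 passed, among them the lists just named, with camera adjusted p of 0.000575, 0.00282, 0.00369 and 0.00378 in this order. The estimated-correlation adjusted p was 0.0781 for the AhR response and for plasma cell genes, 0.115 for heat shock, 0.371 for antigen presentation, 0.616 for ribosomal proteins and 0.0553 for histones. Adjusted over the list alone, 28 glycolysis and hypoxia genes, 23 cholesterol genes, 34 G1/S genes and 31 ATF4 genes passed, the same numbers as adjusted over all genes. For the chemokine and germinal centre lists the median and mean were negative and the test positive, for p53 targets the median alone was negative, and for G2/M genes the median alone was positive, none of them called. None of the lists of other cell types was called. Of 6 myeloid markers 4 rose and 0 fell, with ITGAM at 12.2 ± 0.558 and 33.7 ± 1.02 CPM, of 6 T and NK cell markers 0 rose and 4 fell (median -0.94), and of 6 fibroblast and endothelial markers 1 rose and 3 fell (median -0.94).

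**Figure D2:**
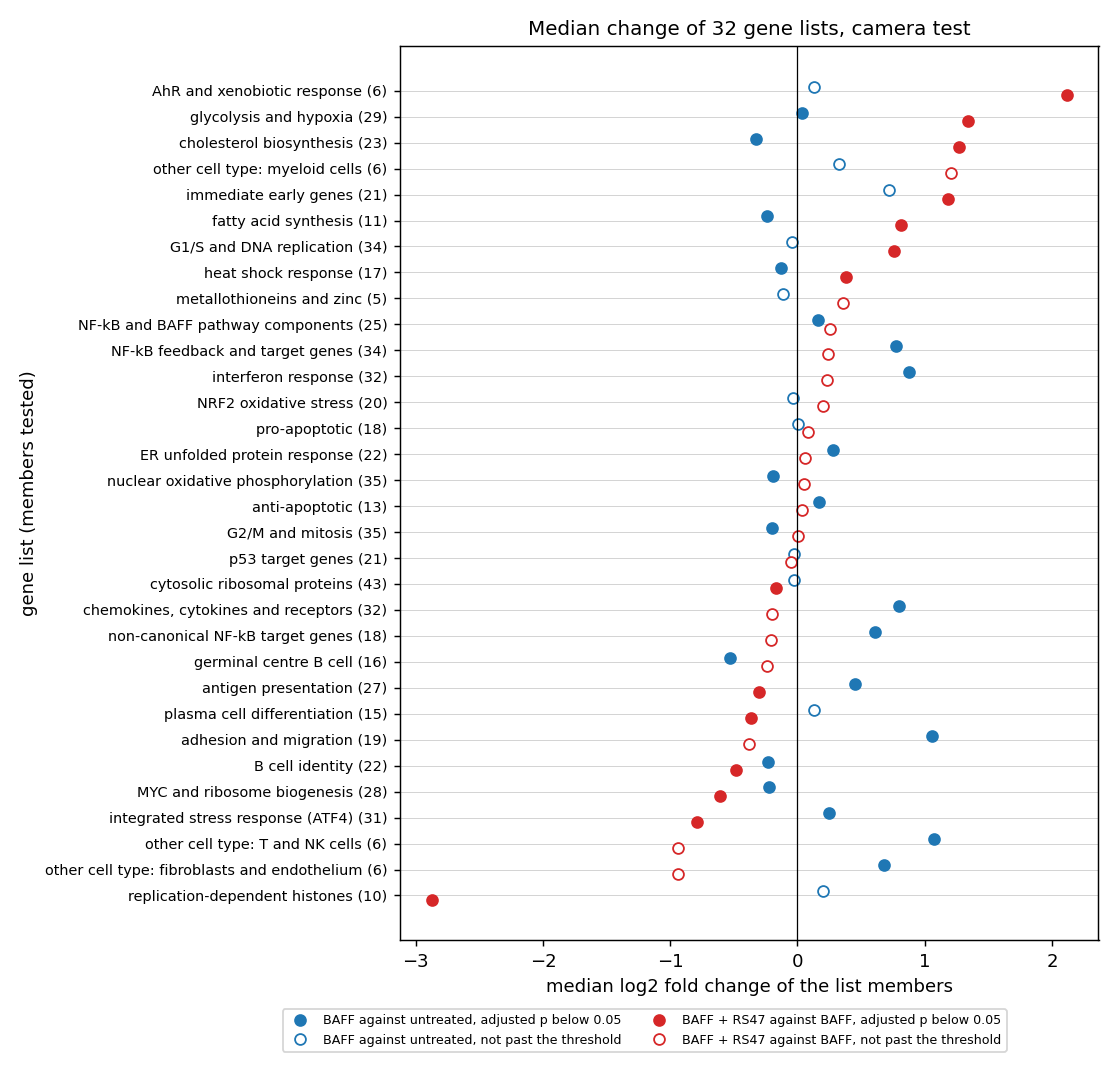
Median log2 fold change (horizontal axis) of the members of 32 gene lists for BAFF against untreated (blue) and BAFF with RS47 against BAFF (red); filled points had a camera adjusted p under 0.05. Glycolysis and hypoxia genes had a median of 1.34 with RS47, and histone genes one of -2.87.

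The design set RS47 against BAFF-induced genes to ask how specific it was. Of the 3434 genes raised by BAFF, 1810 fell with RS47 and 1117 rose further, against 1407.6 and 1316.2 if the comparisons were independent. Their median change with RS47 was -0.20 ± 0.006 (SD, n = 3 RS47 libraries), against -0.03 for all genes tested. The 740 genes raised 2-fold or more fell more, by a median of 1.28 on the log2 scale. Of them 515 passed as lowered and 103 as raised further, against 303.3 and 283.6 if the comparisons were independent. Among these, YAP1, ELFN2, MCC and P2RX7 changed by -3.84, -2.81, -3.98 and -3.09. Of the 740 genes 348 stayed above the untreated level, 131 lay below it and 261 were not told apart from it. A mean logCPM under 3 was found for 577 of them, and the median was not split by expression level. For such weakly expressed genes, background in the BAFF libraries was not told apart from a response to BAFF, so neither was its reversal.

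Of the 3601 genes lowered by BAFF, 1645 rose with RS47 and 1341 fell further, against 1380.2 and 1476.1 if the comparisons were independent. The median change was 0.05 ± 0.008 (SD, n = 3 RS47 libraries), against -0.03 for all genes tested. Of the 104 genes lowered 2-fold or more, 40 rose and 34 fell further, against 39.9 and 42.6. The number that rose was thus close to that of independent comparisons. JCHAIN rose by 0.54 (SE 0.02) and ID3, an inhibitor of E proteins, by 1.60 (SE 0.08), whereas MYC and NCKAP1 were lower with RS47 than with BAFF alone, MYC at 91.8 ± 4.63 CPM. Of the genes that RS47 changed, 3503 of 9416, or 37.2% (Wilson 95% interval 36.2 to 38.2%, counting error only), were not called for BAFF, against 4836 of all 11871 genes tested, or 40.7%. PAX5 was changed by RS47 and not called for BAFF, at 344 ± 4.99 CPM without and 336 ± 1.38 CPM with BAFF. A gene not called for BAFF is not shown to be unaffected by it.

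Both comparisons share the BAFF libraries, which alone pulls their fold changes in opposite directions. Simulated libraries with the measured BAFF effects and no RS47 effect gave at most 2 genes raised and lowered, against 1810, and a covariance of -0.01 across genes, against -0.20. The correlation in these libraries was -0.11, against an observed -0.33. On average 1.65 genes were called for RS47 in them, so hardly any gene could be both raised and lowered. The count of 2 thus bears only on the sharing of libraries, not on whether RS47 acted more on genes raised by BAFF. With no effect of either agent the simulated covariance was -0.01 and the correlation -0.50. Lists of the sizes of the genes raised by BAFF and of those lowered with RS47, drawn independently, would share 1407.6 genes, against 1810. With genes called from 2 BAFF libraries and RS47 measured against the third, the median for genes raised by BAFF was between -0.21 and -0.20. Neither the simulation nor the held-out libraries cover a deviation common to all BAFF libraries, as from a shared culture. On the FPKM scale the medians were smaller, -0.07 for genes raised by BAFF, with 1171 of them lowered by RS47, and -0.86 for 132 genes raised 2-fold at a pseudocount of 1.

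**Figure D3:**
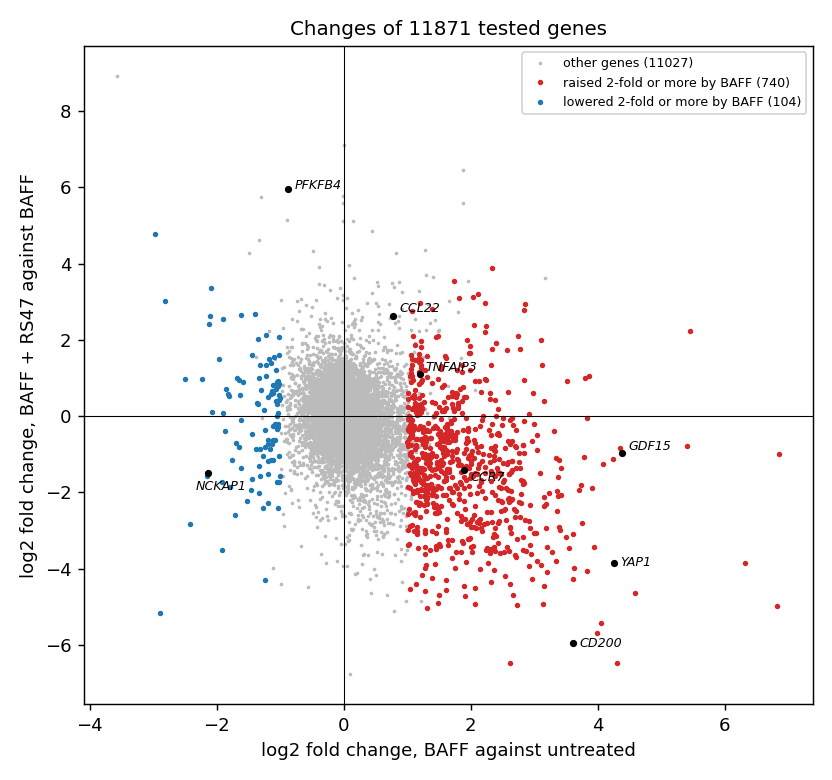
Log2 fold change with BAFF against untreated (horizontal) and with RS47 in BAFF-treated cells (vertical) for 11871 genes, each a point; red marks the 740 genes raised and blue the 104 lowered 2-fold or more by BAFF. Of the red points 515 were lowered with RS47 past the threshold and 103 were raised further, against 303.3 and 283.6 if the comparisons were independent.

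The third comparison measured how far cells given both BAFF and RS47 were from untreated cells. NF-kB feedback and target genes were higher in 30 of 34 cases, TNFAIP3 by 2.29 (SE 0.02) and LTA, the gene of lymphotoxin alpha, by 3.19 (SE 0.07). CD40 was higher by 1.37 and NFKB2 by 0.87, and RELB differed by -0.23 (SE 0.03, edgeR adjusted p = 3.27e-08). Interferon genes were higher in 25 of 32 cases. Of 6 myeloid markers 5 were higher, each by 2-fold or more (median 1.73), a list that camera did not call (adjusted p = 0.151). Of 6 fibroblast and endothelial markers 3 were higher and 3 lower, and of 6 T and NK cell markers 1 was higher and 2 lower, neither list called.

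Glycolysis and hypoxia genes were higher in 27 of 29 cases, with P4HA1, a collagen prolyl hydroxylase, at 249 ± 3.86 CPM against 33.8 ± 0.0273 CPM, and cholesterol biosynthesis genes in 20 of 23. B cell identity genes were lower in 17 of 22 cases, germinal centre genes in 10 of 16 and MYC and ribosome biogenesis genes in 27 of 28, with a difference of -1.91 for MYC on the log2 scale. CDKN1A, a cell cycle inhibitor, was higher by 3.17 (SE 0.09), while p53 targets as a list were not called, with a negative median of -0.11 beside a positive mean of 0.18 and test (camera adjusted p = 0.71). LRRC32, a TGF-beta binding receptor, had 13 counts in untreated libraries and 1043 with both agents, a ratio of 77.4 with a 95% counting interval of 45.1 to 146. UNC5C, a netrin receptor gene, differed by -5.38 (SE 0.23) and DEPTOR, an mTOR inhibitor, by -3.45 (SE 0.09).

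By the edgeR quasi-likelihood test 9353 genes differed, 4582 higher and 4771 lower, with 1082 and 1062 of 2-fold or more. Without both libraries that stood apart 8991 were called. The authors' deposited table has 8765 genes with an adjusted p-value under 0.05, among 16300 genes with a p-value, a wider set than was tested here. Camera called 23 of 32 lists, with adjusted p = 3.20e-41 for glycolysis and hypoxia and 4.97e-16 for NF-kB feedback and target genes. With an estimated correlation 16 passed, among them the lists just named, with camera adjusted p of 0.000729 and 0.00395 in this order. The 7 that did not had estimated-correlation adjusted p of 0.103 for G2/M, 0.0955 for pathway components and for anti-apoptotic genes, 0.34 for antigen presentation, 0.459 for ribosomal proteins, 0.311 for heat shock and 0.0682 for non-canonical targets. The anti-apoptotic list was called upward with a mean of 0.33 and a median of -0.02. Adjusted over the list alone, 34 NF-kB targets, 30 interferon genes, 28 glycolysis and hypoxia genes and 22 B cell identity genes passed, the same numbers as adjusted over all genes. RS47 was not given without BAFF in these libraries, so its effect on cells without BAFF was not measured. The sample titles name no solvent control, so an effect of any solvent given with RS47 was not separated from that of RS47.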

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

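Leaving out both libraries that stood apart, the restrictions to a mean logCPM of at least 3 or 5 and all alternatives for 2-fold results were tests chosen only after the results were seen. The counts of changed genes without a fold threshold stayed within 1.5 times of their values under the other normalizations, filters and tests, and without any single library. Replicate numbers did not pair the libraries. Deviations of same-numbered libraries correlated at -0.06, 0.11 and 0.10 for untreated with BAFF and at 0.32, -0.37 and -0.26 for untreated with BAFF and RS47, and at -0.07, -0.125 and -0.06 for both BAFF groups, and not every library correlated best with its own number. With a replicate block 6958, 9376 and 9302 genes were called and list calls stayed at 21, 14 and 23. A 2-fold threshold left 844, 2128 and 2144 genes, of which 201, 985 and 1169 had a mean logCPM of at least 3 and 76, 500 and 619 one of at least 5. The balance of rises and falls without a fold threshold depended on the scaling or input. BAFF against untreated turned to 3598 rises and 3409 falls by library size. RS47 against BAFF turned to 4250 rises and 3753 falls with FPKM at a pseudocount of 1, and to 4236 and 3746 at 0.1. BAFF with RS47 against untreated turned to 4698 and 4671 with DESeq2 size factors, 4511 and 4488 with DESeq2, and 4122 and 4006 or 4115 and 4014 with FPKM. The excess of 2-fold falls with RS47 narrowed to 465 rises and 520 falls at a mean logCPM of at least 3 and turned to 271 and 229 at 5 or more.

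The median change with RS47 of genes raised by BAFF was -0.186 with DESeq2 size factors, -0.244 with no low-count filter, -0.167 with the 1 CPM filter, -0.192 with 6 libraries, -0.069 with FPKM at both pseudocounts, -0.212 without both libraries, -0.236 at a threshold of 0.01, -1.278 for 2-fold rises, and -0.208 and -0.209 against held-out BAFF libraries 1 and 3. Single libraries left out gave -0.232 to -0.209, all beyond the value of -0.201 with 9 libraries, and more genes then passed the filter. For genes lowered by BAFF it was 0.067 with DESeq2 size factors, 0.043 by library size, 0.071 with DESeq2, 0.065 without the filter, 0.064 and 0.077 with FPKM at pseudocounts 1 and 0.1, 0.089 for 2-fold falls (-0.221, 0.086 and 0 against held-out BAFF libraries 1, 2 and 3, so its sign is not settled), 0.041 against held-out library 1, and 0.041 to 0.059 without single libraries. Genes raised by BAFF and lowered with RS47 numbered 1171 and 1141 with FPKM and 421 at 2-fold. The share of RS47 changes not called for BAFF was 42.08% with DESeq2, 39.94% without the filter, 40.22% and 40.49% with FPKM, 40.05% without both libraries, 46.19% at 0.01, 75.05% with a 2-fold threshold in both comparisons, and 36.12% to 42.02% without single libraries. Of all 11871 genes, 5842 were called for BAFF at 0.01 and 844 (7.11%) at 2-fold. The shares of 46.19% and 75.05% thus lie below the shares of all genes not called at these thresholds. Of the 2128 genes changed 2-fold by RS47, 831 (39.05%) were not called for BAFF at any size, against 40.74% of all genes tested.

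At 2-fold, FPKM with a pseudocount of 1 gave 149, 752 and 823 genes in the 3 comparisons, 132 raised by BAFF and 101 of these lowered with RS47 at a median of -0.859; a pseudocount of 0.1 gave 304, 1224, 1367, 262, 186 and -0.998. A pseudocount shrinks the fold of low values by construction. The FPKM input also kept only genes with an FPKM of at least 1 in 3 libraries, which left 9895 genes. The median of all genes raised by BAFF was -0.069 at both pseudocounts, so the size of the pseudocount did not set it. The shares of the filter and of the FPKM scale in these smaller values were not separated. The median for 2-fold rises was -1.351 without the filter, -1.201 with the 1 CPM filter, -1.346 with 6 libraries and -1.363 to -1.267 without single libraries. Lists called for RS47 against BAFF numbered 8 with an estimated correlation and 31 with fry, which does not compare a list with other genes. MAP3K14 in that comparison turned from 0.003 to -0.005 by library size and -0.023 without both libraries, and ranged from -0.03 to 0.069 without single libraries. Over the genes named, 2738 values kept direction and call, 28 lost the call, all for NFKB2 with RS47 or RELA and TRAF3 with BAFF, and 2 gained it. Of the list values 236 kept their call, 19 lost and 33 gained it. Where no construction is named, the cause was not tested. At this depth 1 count is about 0.05 CPM, so genes under 1 CPM rest on few counts.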

Other observations

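Of the tests in this part, those on held-out BAFF libraries, on NF-kB target genes, on well expressed genes, on markers of other cell types and on well expressed genes of both libraries that stood apart were chosen only after the results were seen. A search of 2073 functional terms was also made after the lists had been seen. Some of the terms given here share genes with lists already described and are not independent of them. WARS, SARS and SLC7A11 belong to the ATF4 list, and HLA-DRA, HLA-DQA1 and CD74 to the antigen presentation list. With BAFF, 62 of 83 genes of mitochondrial translational elongation were lower and 1 was higher (median -0.23, camera adjusted p = 6.52e-06, adjusted p = 0.485 with an estimated correlation), with MRPL4, PTCD3, MRPS27 and MRPS5 having the smallest p. Spliceosome genes were lower in 74 of 127 cases and higher in 16 (median -0.14, camera adjusted p = 0.00031, adjusted p = 0.471 with an estimated correlation), among them the splicing factors HNRNPA3, SRSF1, SRSF5 and SRSF7.

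With RS47 added to BAFF, 23 of 33 genes of tRNA aminoacylation were lower and 6 higher (median -0.46, camera adjusted p = 2.04e-09, adjusted p = 0.183 with an estimated correlation), including WARS, SARS, IARS and MARS. Amino acid transporters were lower in 11 of 19 cases and higher in 5 (median -0.66, camera adjusted p = 0.000698, adjusted p = 0.538 with an estimated correlation), with SLC7A11, SLC43A1, SLC3A2 and SLC1A5 leading. All 13 genes of the MHC class II complex were higher with BAFF (median 0.36, camera adjusted p = 9.68e-10, adjusted p = 0.154 with an estimated correlation) and 12 of 13 were lower with RS47 (median -0.58, camera adjusted p = 0.000698, adjusted p = 0.654 with an estimated correlation). With an estimated correlation 0 terms were called in any comparison, against 117, 41 and 123 with the preset one.

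Genes raised 2-fold by BAFF fell with RS47 by a median of 1.28 on the log2 scale. Chance values of single BAFF libraries are argued against as the whole cause, since the median was -1.243 or lower against each held-out library. A deviation common to all BAFF libraries, as from a shared culture, would remain in a held-out library, and the labels do not exclude it. A general fall at this expression level is also argued against as the whole cause, since the lowest of 1000 matched random sets had a median of -0.368. Background in the BAFF libraries was not excluded for the 577 of 740 genes with a mean logCPM under 3. Whether NF-kB targets took part to the same degree stays open: 8 of 16 such genes raised 2-fold fell (50%) and 6 rose further, against 507 of 724 other genes lowered (70.03%, Fisher's exact test, two-sided, p = 0.101). The median change with RS47 was -0.189 for these targets and -1.292 for the other genes. Mean logCPM also differed, 4.855 against 1.473, so expression level cannot be separated from this difference.

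BAFF raised 740 and lowered 104 genes 2-fold or more. A low background in the BAFF libraries is argued against for well expressed genes, where 163 of 201 such changes were rises (81.09%). For RNA of another cell type, at most 25% of a type's fixed markers rose 2-fold, but markers that failed the filter counted as not raised. Of those past the filter, 3 of 6 T and NK cell and 3 of 4 epithelial markers rose 2-fold, so this share does not decide. Levels, with TMM factors taken over the unfiltered table, argue against such RNA as the whole cause. With BAFF, 6 of 15 T and NK cell and 3 of 12 epithelial markers exceeded 1 CPM. So did 4 of 14 fibroblast and endothelial and 3 of 14 myeloid markers. COL1A1 was at 172 CPM but COL1A2 at 0.203 CPM. For weakly expressed genes background cannot be told apart from a response: 2256 genes at 0.1 to 1 CPM with RS47 had a median log2 change of 0.513 with BAFF, but of 0.25 to 0.806 between pairs of libraries, 0.68 against untreated replicate 3 and 0.317 and 0.348 against the others. That median is above the bound of 0.5 set beforehand, past which background was to count as the explanation, but because the library pairs straddle the bound, a stricter rule over pairs was adopted after the value was seen.

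Untreated replicate 3 and BAFF with RS47 replicate 2 deviated from their groups together (r = 0.558 across 11871 genes, which are not independent replicates). GC content and transcript length are argued against as the whole cause, since over 11730 genes with both values r was 0.567 before and 0.568 after either trend was removed. Loss of genes with few counts is also argued against as the whole cause, with r = 0.424 among genes with a mean logCPM of at least 3. A shared preparation step may be a source, but no label gives one, and no biological explanation was tested.

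Other splits of the libraries were counted for each comparison. BAFF against untreated gave 7035 genes and the highest other split 1, RS47 against BAFF 9416 and 0, and BAFF with RS47 against untreated 9353 and 0 by edgeR. Only 1 of 10 splits reached the real number in each, and 10 splits are too few for a share under 0.05.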
